A study of Homo sapiens with 6 samples.

How the data were processed

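Polyadenylated RNA of L3.6pl pancreatic cancer cells was sequenced in 6 libraries, 3 of parental cells (Par) and 3 of gemcitabine-resistant cells (GemR), after 24 h in vehicle. RNA was extracted with QIAzol and libraries were made with the TruSeq RNA kit, which does not mark strand, per the labels' protocols. Reads were processed with STAR 2.6.0c, HTSeq 0.11.1 and DESeq2 on hg38, per the submitters' processing notes. The DESeq2 version, the gene annotation and the settings of these tools are not given in the sources used here. Samples were put in groups by their titles.

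The main table holds a signal per gene and library, normalised counts that the authors made by dividing read counts by 1 size factor per library. The authors also deposited a table of their DESeq2 comparison, with group means of this signal, log2 fold changes and their standard errors on the log2 scale, a test score (the Wald statistic) and p-values with adjusted p-values, per the file headers. Its group means differed from those of the normalised counts by at most 6.67e-06. It was used only to be set beside the values computed here.

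In each library 100% of the deposited values above 0 were whole multiples of 1 step (tolerance 0.001 of a read), so the reads behind them could be recovered. Recovered totals were 11952974, 10493323 and 9531113 reads for Par replicates 1 to 3 and 14694112, 15458808 and 12945725 for GemR. These are reads assigned to genes, and a floor of 3 reads corresponds to 2.38 to 3.86 normalised counts. The 10 most abundant genes took 3.07 to 3.45% of the reads of a library. Intervals of read ratios are exact at a confidence level of 95% and cover counting error only, since the reads carry no molecular identifiers. Libraries of a group differed by 2.00 to 3.85 times the chi-square expected from counting noise, so none was taken as a repeat of another.

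The table lists 26485 genes, of which 28 have symbols turned into dates by a spreadsheet and none is a gene with an MT- prefix. The main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(normalised count + 1), over the 13147 genes with a mean normalised count of 10 or more, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. On the recovered reads, edgeR 4.0.16 (quasi-likelihood, TMM) called 5675 genes, 5557 of them also called by limma, and DESeq2 1.42.0 called 4731, 4724 of them also called by limma.

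Gene lists of 32 pathways, states and other cell types were fixed in advance, and the 27 with at least 5 tested genes were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move, on balance, in one direction. On the edgeR and DESeq2 values camera was run in its preranked form (cameraPR), on z scores made from the p-values with the sign of the change. These runs are counted among the camera settings, though their statistic differs. Genes were placed on GRCh38 by symbol or older symbol through the RefSeq annotation, which gave a position to 12936 tested genes (98.4%). A scan took the median log2 fold change of 21 neighbouring tested genes and kept windows above the 97.5th percentile of the highest window, or below the 2.5th percentile of the lowest window, of 1000 shuffles of gene order, which were 0.36 and -0.43. GC content and transcript length were taken from GENCODE v29 transcripts.

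The named-gene rule took STIM1, STIM2, ORAI1, ORAI2, ORAI3, RRM1, SLC29A1, DCK and CDA whatever their values. It took also the 10 largest rises and the 10 largest falls among called genes with a mean of 100 or more in the higher group and groups that do not overlap. For each list it took up to 4 called members with the largest change and a mean of 50 or more in the higher group, and up to 2 members that did not pass, and for each shifted region the 5 members with the highest mean count. The groups, tests, lists, named-gene rule and first set of other settings were chosen before the data were examined. These settings were pseudocounts of 0.5 and 8, no filter and a minimum mean of 50, TMM, equal totals and quantile scaling, limma without trend, the replicate number as a block, each library left out in turn, windows of 11 and 41 genes, a 2-fold minimum and an adjusted p under 0.01. Reads thinned to equal depth and the tests without the genes of shifted regions were added after the data were seen.

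The gene tests were tried on simulated data, drawn from the means and totals of these libraries with 200 genes changed and 13143 tested. Far fewer genes were thus changed than the 5647 called in the real data. For the comparison of GemR with Par, limma called 72.7% of the genes changed 1.3-fold, 96.9% of those changed 2-fold and 100% of those changed 4-fold, with 12 unchanged genes among 188 calls. For edgeR the shares were the same, with 10 unchanged genes among 186 calls, and DESeq2 called 65.2, 90.8 and 96.9%, with 4 among 169. Camera and the scan were run on a separate draw, in which only a list and a stretch of neighbouring genes were shifted. Camera found the shifted list and 0 others. The scan found 2 regions, at least 1 of them higher on the chromosome of the shifted stretch. Genes were drawn independently of each other, so this draw cannot check the correlation that camera presets. With no change simulated, limma called 0 genes and the scan found 0 regions.

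Reads of near-identical genes (the HLA, AKR1C and keratin 6 genes, and the ferritins with their pseudogenes) and of overlapping genes can be misassigned, and the values of such genes are uncertain. Among the genes named in the text, this holds for STIM1, FOSL2, VLDLR, PSMB8, HLA-F, LIF, CDH2, TGFB2, SNAP25, CTGF, CORO1A and MUC5B, which overlap antisense genes. It holds for BHLHE41, ORAI2, LOX, RPA3, FN1, PFKM, GINS2, RPL27A, ACTN4, XRCC1, BMI1, ASNS, DUSP6, ITPR1, TNFAIP3, KDELR1, KDELR3, SEC61A1, S100A4, BHLHA15, FTH1, PLTP, CLDN2 and TRIM6, among others, which overlap other genes. Further named genes, MSLN, CXCL5, COL3A1 and ABCG2 among them, overlap unnamed transcripts, pseudogenes or small RNAs. The positions of named genes are those of the annotation used here, which may differ from the one used for counting. DNA copy number was not analysed here. The values of some genes that the rule takes are not reported here.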

Results

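Messenger RNA was sequenced from L3.6pl, a human pancreatic cancer cell line, in a parental form (Par) and a gemcitabine-resistant form (GemR) that was kept in 64 nM gemcitabine, a cytidine analogue used as chemotherapy. Each group held 3 libraries, all from cells given vehicle (DMSO) for 24 h before harvest. The reads assigned to genes ranged from 9531113 to 11952974 in the Par libraries and from 12945725 to 15458808 in the GemR libraries, so every GemR library was deeper than every Par library. Of 26485 genes listed, 19188 had a read in at least 1 library and 13147 had a mean normalised count of 10 or more and were tested. Values are normalised read counts as mean ± SD over n = 3 libraries per group. Fold changes are on the scale of log2(normalised count + 1), which understates the change of genes with few reads. The kit does not mark strand, so the value of a gene that overlaps another may include reads of its neighbour. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

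The comparison of GemR with Par asked which genes were expressed differently in the resistant cells, and STIM1 was the gene the study was named after. The labels give gemcitabine maintenance for GemR only. Resistance, exposure to the drug and any other difference between these forms of the line therefore cannot be told apart here. STIM1, the calcium sensor of the endoplasmic reticulum that opens ORAI channels in the plasma membrane when the store empties, rose 14.03-fold in GemR, from 405 ± 47.3 normalised counts to 5671 ± 203 (SD, n = 3 each; log2 fold change 3.81, SE 0.06, limma adjusted p = 5.01e-29). RRM1, which encodes the large subunit of ribonucleotide reductase, an enzyme that gemcitabine inhibits, rose 16.6-fold, from 3522 ± 56.2 to 58613 ± 2185 (log2 fold change 4.06, adjusted p = 5.28e-33). The channel genes ORAI2 and ORAI3 rose 1.53-fold, from 157 ± 8.64 to 242 ± 29.3 (adjusted p = 1.27e-05), and 1.36-fold, from 311 ± 32.9 to 422 ± 20.4 (adjusted p = 6.55e-05). STIM2, the paralog of STIM1, stood at 292 ± 4.91 in Par and 296 ± 11.9 in GemR (log2 fold change 0.02, adjusted p = 0.859). ORAI1, the main channel of this pathway, stood at 590.3 ± 11.8 and 527 ± 56.2 (log2 fold change -0.17, adjusted p = 0.0637). Neither passed the test. ORAI1 passed, lower, without GemR replicate 3 (log2 fold change -0.25), with equal totals, with the replicate number as a block and with thinned reads, and the sign of STIM2 turned without GemR replicate 2 and with thinned reads. STIM1 lies on chromosome 11 from 3854604 to 4093210 and RRM1 beside it from 4094685 to 4138932 (GRCh38). RRM1 overlapped no other annotated gene, whereas STIM1 overlaps STIM1-AS1, whose reads cannot be separated from its own. RRM1 took 0.0284 to 0.0293% of the reads assigned to genes in the Par libraries and 0.453 to 0.486% in the GemR libraries.

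Among the 23 tested genes of the store-operated calcium entry list, 3 rose, 6 fell and 14 did not pass, with the same counts adjusted over the list alone. With equal totals 10 of them fell, and with quantile scaling 5. The genes that rose were STIM1, ORAI2 and ORAI3. CRACR2B, a calcium-binding regulator of ORAI channels encoded in a region of chromosome 11 where most genes fell, dropped 2.19-fold, from 183 ± 9.89 to 83.99 ± 15.8. ITPR1, an inositol trisphosphate receptor that releases calcium from the store, fell 1.62-fold and NFATC1, a transcription factor activated by calcineurin, fell 1.57-fold. ATP2A2, the pump that refills the store, stood at 4569.8 ± 235 in Par and 4279.6 ± 80.9 in GemR (adjusted p = 0.133), though it passed without Par replicate 1 (log2 fold change -0.14). SARAF, which limits calcium refilling, stood at 4389 ± 125 and 4063 ± 45.5 (adjusted p = 0.0618) and passed, lower, with equal totals, with the block and in DESeq2. As a set the list did not pass camera (adjusted p = 0.495).

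**Figure D1:**
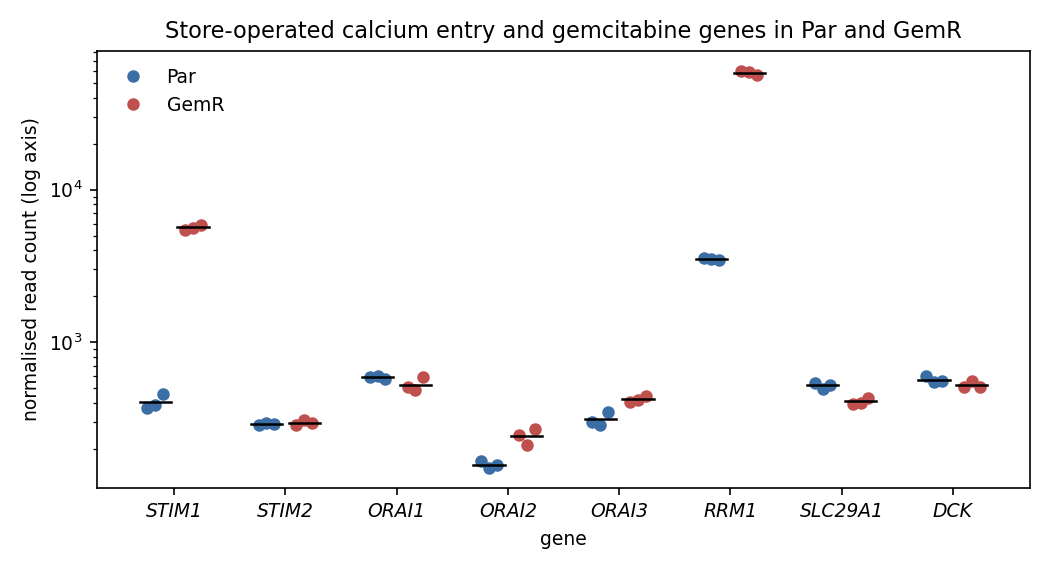
Normalised read counts (log axis) of 8 genes of store-operated calcium entry and gemcitabine handling in the 3 Par and 3 GemR libraries, with 1 point per library and a black bar at the group mean. STIM1 lay near 405 in Par and 5671 in GemR, and RRM1 near 3522 and 58613, while STIM2 lay near 292 and 296.

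Of the 20 tested genes of gemcitabine uptake, activation and targets, 5 rose, 3 fell and 12 did not pass, and the counts were the same adjusted over the list alone. Besides RRM1, the genes that rose included NT5E, the surface 5'-nucleotidase CD73 (1.804-fold, from 193 ± 22.9 to 350.3 ± 50.3), and NT5C3A, a cytosolic pyrimidine nucleotidase (1.28-fold). SLC29A1, which encodes the nucleoside transporter ENT1 that carries gemcitabine into cells, fell 1.27-fold, from 522 ± 25.6 to 410.0 ± 20.98 (log2 fold change -0.35, SE 0.07, adjusted p = 2.60e-04). DCK, the kinase that activates gemcitabine, stood at 569 ± 24.8 in Par and 525 ± 30.7 in GemR (log2 fold change -0.12, adjusted p = 0.184). RRM2, the small subunit of ribonucleotide reductase, stood at 2986 ± 179 and 2819 ± 32.1 (adjusted p = 0.216). CDA, the deaminase that inactivates gemcitabine, had 1 read over the Par libraries and 2 over the GemR libraries, too few to compare at this depth. The list did not pass camera (adjusted p = 0.495), and its median log2 fold change of -0.04 and its mean of 0.22 differed in sign. Of 12 tested ABC drug efflux transporters, 3 rose, 4 fell and 5 did not pass (5 risen and 4 fallen adjusted over the list alone). This list did not pass camera either (adjusted p = 0.841), and its median of 0.04 and mean of -0.08 also differed in sign. ABCG2, a transporter of many cytotoxic drugs, fell 3.06-fold, from 336 ± 29.6 to 110.3 ± 21.6, while ABCC4 rose 1.88-fold and ABCC3 1.47-fold.

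Across all tested genes, 5647 (43.0%) passed an adjusted p of 0.05 in limma, 2741 higher and 2906 lower in GemR, and most of these differences were small, with a median fold of 1.29. A change of at least 2-fold was seen for 289 genes that rose and 377 that fell. In the authors' deposited table, made from the same libraries, 4546 genes had an adjusted p-value under 0.05, 2132 higher and 2414 lower. Over the 13147 genes in both, 99.3% had the same sign of log2 fold change in the authors' deposited table and here (Pearson r = 0.993, Spearman rho = 0.999, across genes, which are not independent replicates). Of the 4419 of these genes that passed in the authors' deposited table, 4413 also passed here, all with the same sign.

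Among genes that passed, with a mean of 100 or more in the higher group and no overlap between the groups, the largest rises were those of MSLN, PTGES, SP6, RRM1, BHLHE41, STIM1, CD70, CRISPLD2, TRIM6 and MAOA. MSLN, which encodes the cell-surface antigen mesothelin, rose from 3.04 ± 0.455 to 113 ± 8.42 (adjusted p = 3.71e-16), where 8 reads over the 3 Par libraries put the ratio of Par to GemR at 0.0272 (95% interval of counting error 0.0117 to 0.0542). PTGES, the enzyme that makes prostaglandin E2, rose 23.6-fold, from 107 ± 3.67 to 2536 ± 143 (adjusted p = 7.48e-30). The transcription factor genes SP6 and BHLHE41 rose 18.2-fold and 15.2-fold, CD70, a ligand of the tumour necrosis factor family, rose 13.3-fold, and CRISPLD2, which encodes a secreted protein, rose 12.1-fold. MAOA, the mitochondrial monoamine oxidase, rose 8.11-fold, from 25.4 ± 3.39 to 212 ± 23.99. TRIM6, a ubiquitin ligase gene near RRM1, rose 10.6-fold, from 22.96 ± 5.42 to 248 ± 7.37, and overlaps TRIM5, so that some of its reads may not be its own.

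By the same limits, the largest falls were those of CXCL5, PLTP, C4BPB, MAGED1, THSD7A, NTRK2, COL3A1, CLDN2, STXBP6 and ANKRD1, several of which left few reads in GemR. CXCL5, a chemokine that attracts neutrophils, fell from 1029.6 ± 109 to 2.63 ± 1.09 normalised counts (adjusted p = 7.95e-26), where 9 reads over the 3 GemR libraries put the ratio of Par to GemR at 402 (95% interval of counting error 211 to 880). PLTP, the phospholipid transfer protein, fell from 489 ± 18.3 to 1.71 ± 0.786, with 6 reads in GemR and a ratio of 285 (130.4 to 777). C4BPB, a chain of the complement inhibitor C4b-binding protein, fell from 151 ± 22.1 to 1.13 ± 0.399, with 4 reads in GemR and a ratio of 132 (51.2 to 487). COL3A1, a fibrillar collagen, fell 30.8-fold, from 3620.3 ± 143 to 117 ± 17.9 (log2 fold change -4.95, SE 0.08, adjusted p = 1.10e-29). THSD7A fell 57.4-fold, from 1418 ± 141 to 23.8 ± 3.79, and MAGED1, a gene of the MAGE family, fell 60.4-fold, from 735 ± 32.96 to 11.5 ± 3.82. The neurotrophin receptor gene NTRK2 fell from 142 ± 9.47 to 2.58 ± 0.783, the tight junction gene CLDN2 from 123 ± 5.93 to 3.22 ± 1.55, STXBP6 from 182 ± 2.301 to 6.51 ± 1.51, and ANKRD1, a target of the coactivator YAP, from 136 ± 4.45 to 4.98 ± 1.77, with 9, 11, 23 and 17 reads over the GemR libraries. PLTP overlaps CTSA and CLDN2 overlaps RIPPLY1 in the annotation, so reads in the shared parts cannot be assigned to either gene.

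STIM1 and RRM1 stood at the edge of a block of neighbouring genes on the short arm of chromosome 11 that rose together. From STIM1 to SBF2-AS1 (3854604 to 9811319, GRCh38), 37 of 41 tested genes rose, 0 fell and 4 did not pass, with a median rise of 3.59-fold (log2 1.84, interquartile range 1.44 to 2.28). RPL27A, a ribosomal protein gene, rose 3.57-fold, from 5087 ± 144 to 18151 ± 982, MRPL17, of the mitochondrial ribosome, 4.18-fold, TRIM68 6.27-fold, IPO7, a nuclear import factor, 2.07-fold, and WEE1, the kinase that restrains entry into mitosis, 1.92-fold, from 619 ± 33.5 to 1189 ± 19.5. The genes on both sides of the block moved the other way. Between 202924 and 3840959, before STIM1, 53 of 66 tested genes fell and 4 rose (median log2 fold change -0.50), and RHOG, the last of them, fell 1.38-fold, from 656 ± 23.4 to 476 ± 21.1. Beyond SBF2-AS1, up to 31790324, 44 of 59 tested genes fell and 7 rose (median -0.50), among them EIF4G2, a translation factor gene, by 1.54-fold and LDHA, lactate dehydrogenase A, by 1.27-fold. In the list of 11p15.4 neighbours fixed in advance, 6 genes rose, 8 fell and 3 did not pass of 17 tested, with the same counts adjusted over the list alone. Its median of -0.38 and the mean of 0.80 differed in sign. The list did not pass camera (adjusted p = 0.295) but passed on the DESeq2 values (preranked camera, 6.03e-11) and in fry (4.65e-05), in a range of 6.03e-11 to 0.536 over the camera settings run. The lower end of this range comes from the preranked form, so the range mixes unlike statistics. The limits of the block and RHOG as its neighbour were chosen after the values were seen.

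**Figure D2:**
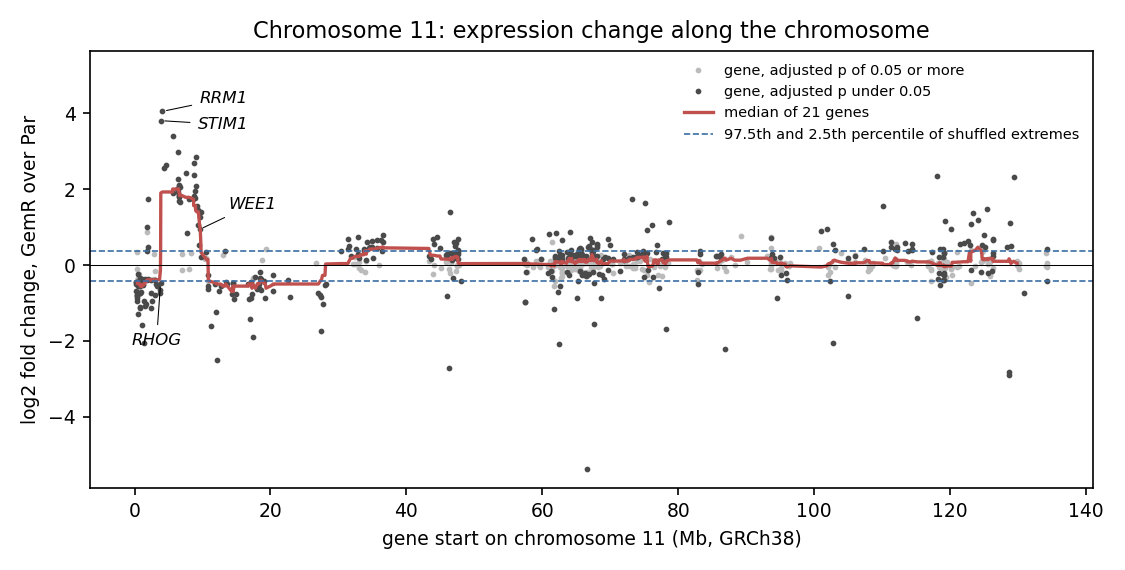
Log2 fold change of GemR over Par for each tested gene along chromosome 11 (gene start in Mb, GRCh38), with dark points for genes with an adjusted p under 0.05, the median of 21 neighbouring genes as a red line and dashed lines at the thresholds from shuffled gene order (0.36 and -0.43). The line rises at STIM1 and RRM1 to a highest window median of 2.01 and lies below the lower threshold in stretches on both sides of the block.

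Chromosome 19 was divided in its middle. Beyond 23 Mb, a span that holds the long arm (23221599 to 58584395), 368 of 487 tested genes fell, 12 rose and 107 did not pass, with a median log2 fold change of -0.48, a fall of 1.40-fold, whereas before 23 Mb 49 of 409 tested genes fell and 80 rose (median 0.07). The division at 23 Mb was placed after the values were seen. The falls included GPI, the glycolytic glucose-6-phosphate isomerase (1.496-fold, from 9689 ± 398 to 6478 ± 285), SPINT2, an inhibitor of serine proteases (1.54-fold), ACTN4, which crosslinks actin (1.38-fold), and the ribosomal protein genes RPS16 (1.44-fold, from 9760.4 ± 732 to 6788 ± 152) and RPL13A (1.44-fold). A scan of 12936 positioned genes in windows of 21 found 11 regions beyond the thresholds set by 1000 shuffles of gene order, 4 higher and 7 lower. Besides the parts of chromosomes 11 and 19 above, these were lower regions on chromosome 1 (6.26 to 9.91 Mb, with ENO1, the glycolytic enolase, down 1.22-fold) and chromosome 6 (3.12 to 8.10 Mb, with SSR1, of the translocon-associated complex, down 1.68-fold). Higher regions lay on chromosome 11 at 32.6 to 45.9 Mb (EHF, an epithelial transcription factor, up 1.39-fold) and 121 to 126 Mb (GRAMD1B, a sterol transporter, up 2.58-fold) and on chromosome 22 at 38.2 to 39.3 Mb (TOMM22, of the mitochondrial import complex, up 1.25-fold). The 778 genes in these regions were 6.01% of those scanned and 10.97% of the genes that passed, and 78.9% of them passed, against 40.99% of the genes elsewhere. The regions were found from the same fold changes, so a higher share inside them was in part fixed by the choice. The number of regions fell to 3 with windows of 11 genes.

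**Figure D3:**
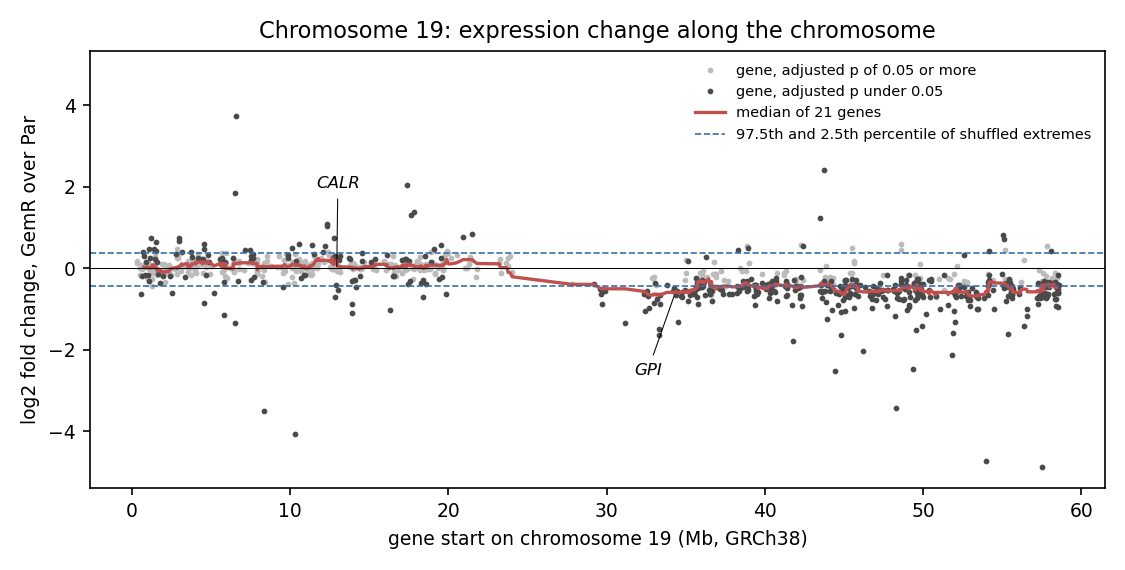
Log2 fold change of GemR over Par for each tested gene along chromosome 19 (gene start in Mb, GRCh38), with dark points for genes with an adjusted p under 0.05, the median of 21 neighbouring genes as a red line and dashed lines at the thresholds from shuffled gene order (0.36 and -0.43). The line stays near 0 before 23 Mb, where the median is 0.07, and below it beyond, where the median is -0.48.

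Of 32 gene lists fixed in advance, 27 had the 5 or more tested genes needed, and 4 passed camera with its preset correlation, 2 lower and 2 higher in GemR. With an estimated correlation between genes 0 of the 27 lists passed in camera, 3 had an unadjusted p under 0.05, and 17 passed fry. Besides the 4 lists, those that passed fry were the immediate early, G1/S, interferon, stem cell, mesenchymal, 11p15.4, DNA damage, NF-kB, NRF2, epithelial, gemcitabine, histone and hypoxia lists. The number that passed also rose to 10 with no filter on low values, 9 with reads thinned to equal depth, 8 without GemR replicate 1 and 7 without GemR replicate 3. These counts cover every list with 5 or more tested genes in that setting. They can therefore include lists of other cell types outside the 27, which are not named here. Without the genes of the shifted regions 9 passed, the immediate early, interferon, stem cell, NRF2 and ribosomal lists besides the 4. The regions were found from the same fold changes, and their removal took all 7 fallen ribosomal genes, 3 of the 4 fallen interferon genes and 2 of the 6 fallen NRF2 genes, so these passes were in part fixed by the filter. The ranges of adjusted p below are over the camera settings run, fry and this filter left out. Genes of the classical subtype of pancreatic tumours, which mark a gut-like epithelial state, were lower in GemR. Of 11 tested, 0 rose, 9 fell and 2 did not pass (1 risen and 9 fallen adjusted over the list alone or with quantile scaling), with a median log2 fold change of -1.38 (camera adjusted p = 1.25e-07; adjusted p = 0.271 with an estimated correlation). TSPAN8, a tetraspanin, fell 7.505-fold, from 870.3 ± 47.1 to 115 ± 11.3, GATA6, a transcription factor of the pancreatic lineage, 4.43-fold, from 625 ± 35.7 to 140.3 ± 7.72, and CEACAM6, an adhesion molecule encoded in the lower part of chromosome 19, 3.48-fold. ST6GALNAC1, a sialyltransferase, fell from 116 ± 9.402 to 4.44 ± 2.28, with 16 reads over the GemR libraries (ratio of Par to GemR 25.5, 95% interval of counting error 15.5 to 45.2). AGR2, a protein disulfide isomerase, stood at 355 ± 5.04 and 409.9 ± 53.4 (adjusted p = 0.0539) and passed, higher, without GemR replicate 3 (log2 fold change 0.30), with a minimum mean of 50, with quantile scaling, with the block and in edgeR. Genes of the basal-like subtype, many of them squamous, were mostly higher, with 10 risen, 3 fallen and 2 not passed of 15 tested, and the same counts adjusted over the list alone (median 0.34, camera adjusted p = 0.0446; adjusted p = 0.474 with an estimated correlation). FGFBP1, a carrier of fibroblast growth factors, rose 3.68-fold, from 1786 ± 134 to 6560.1 ± 103, and KRT6A, a keratin with near-identical paralogs, 2.92-fold, while KRT5, a keratin of basal epithelia, fell 10.4-fold, from 4797 ± 177 to 464 ± 52.4. The call of the basal-like list was lost without Par replicate 1 (adjusted p = 0.0577), without GemR replicate 3 (0.0578), with the replicate number as a block (0.0522), with quantile scaling (0.0685) and on the DESeq2 values (0.0552). It was lost also with a minimum mean of 50 (0.139), where the list mean went from 0.24 to 0.09, and its adjusted p ranged from 0.0107 to 0.474.

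Genes of the unfolded protein response and endoplasmic reticulum stress were lower in GemR, with 2 risen, 21 fallen and 7 not passed of 30 tested and the same counts adjusted over the list alone (median log2 fold change -0.22, camera adjusted p = 1.90e-05; adjusted p = 0.358 with an estimated correlation). CHAC1, a glutathione-degrading enzyme induced by ATF4, fell 1.87-fold, from 377 ± 19.3 to 201 ± 13.6, ASNS, asparagine synthetase, 1.73-fold, from 5746 ± 244 to 3327 ± 265, VLDLR, a lipoprotein receptor, 1.74-fold, and SEL1L, of the machinery that clears misfolded proteins, 1.52-fold. CALR, a calcium-binding chaperone of the endoplasmic reticulum, stood at 17700.0 ± 661 and 16849 ± 783 (adjusted p = 0.257). Of 22 calcium-responsive immediate early genes, 4 rose, 9 fell and 9 did not pass (4 and 10 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0542). It passed without Par replicate 2 (0.0497), GemR replicate 1 (0.0384) or GemR replicate 3 (0.0322), and also with no filter (0.0228), on the DESeq2 values (0.00859) and with thinned reads (0.0363), in a range of 0.00859 to 0.358. CTGF, a matricellular protein and YAP target, fell 7.65-fold, from 161 ± 3.36 to 20.8 ± 6.89, FOS 2.95-fold, from 968 ± 14.3 to 329 ± 29.9, CYR61 2.18-fold and FOSL2 2.04-fold. DUSP6, a phosphatase of the ERK pathway, stood at 4218 ± 82.8 and 3957 ± 164 (adjusted p = 0.129).

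Genes of MHC class I antigen presentation were higher in GemR, with 11 risen, 3 fallen and 1 not passed of 15 tested and the same counts adjusted over the list alone (median 0.36, camera adjusted p = 0.00241; adjusted p = 0.474 with an estimated correlation). PSMB9 and PSMB8, subunits of the immunoproteasome, rose 1.89-fold, from 149 ± 17.6 to 281 ± 7.45, and 1.53-fold, from 649 ± 59.3 to 989 ± 41.5. HLA-B rose 1.66-fold, from 1189 ± 89.7 to 1971 ± 9.45, and HLA-F 1.75-fold, though reads can be misassigned between the near-identical HLA genes. Of 32 interferon-stimulated genes, 15 rose, 4 fell and 13 did not pass (17 and 4 adjusted over the list alone). The list did not pass (camera adjusted p = 0.0542), but passed without Par replicate 2 (0.0497), with no filter (0.0117) and with thinned reads (0.0378), in a range of 0.0117 to 0.358. OASL and OAS1, of the oligoadenylate synthetase family, rose 4.26-fold and 2.103-fold, and BST2, the restriction factor tetherin, 4.13-fold, from 21.5 ± 2.94 to 91.9 ± 11.4. IFITM2, which blocks virus entry and is encoded in the lower region before STIM1, fell 1.94-fold. Among 16 NF-kB-dependent cytokine genes, 4 rose, 4 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.495). LIF, a cytokine of the interleukin-6 family, rose 1.71-fold, from 1031 ± 45.7 to 1759 ± 12.3, while TNFAIP3, an inhibitor of NF-kB, fell 1.95-fold and CXCL3 1.58-fold.

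**Figure D4:**
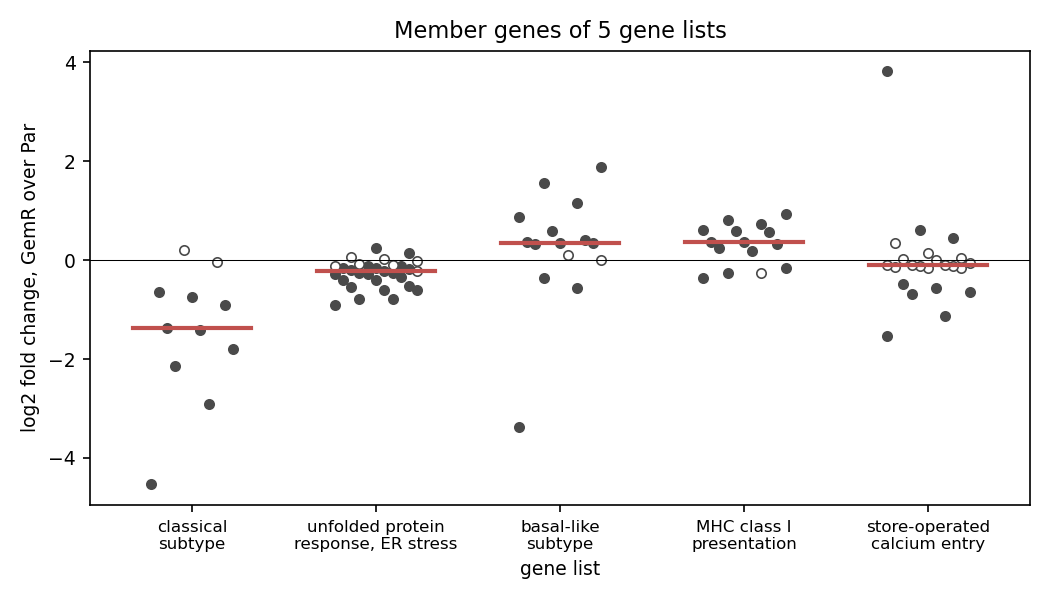
Log2 fold change of GemR over Par for each tested member of 5 gene lists, with filled points for genes with an adjusted p under 0.05, open points for the others and a red line at the list median. The medians are -1.38 for the classical subtype, -0.22 for the unfolded protein response, 0.34 for the basal-like subtype, 0.36 for MHC class I presentation and -0.11 for store-operated calcium entry, where STIM1 stands alone at 3.81.

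Most proliferation genes did not pass. Of 33 G2/M genes, 3 rose, 6 fell and 24 did not pass (camera adjusted p = 0.627). The kinesin gene KIF2C rose 1.198-fold, CENPA, the centromeric histone, fell 1.18-fold, and TOP2A, topoisomerase II alpha, stood at 12591 ± 355 and 11912 ± 248 (adjusted p = 0.177) and passed, lower, with quantile scaling. Of 36 G1/S and S phase genes, 10 rose, 2 fell and 24 did not pass (camera adjusted p = 0.0542), and with equal totals 9 rose and 4 fell. This list passed without GemR replicate 2 (0.0464) or 3 (0.0332), with no filter (0.0190), on the DESeq2 values (0.0137) and with thinned reads (0.0446), in a range of 0.0137 to 0.521. Besides RRM1, GINS2 and RFC2, which act at the replication fork, rose 1.32-fold and 1.21-fold, and CCNE1, cyclin E1, encoded in the lower part of chromosome 19, fell 1.42-fold. Targets of p53 went both ways, with 5 risen, 7 fallen and 15 not passed of 27 (camera adjusted p = 0.676). GDF15, a stress-induced cytokine, fell 1.64-fold, from 1147 ± 60.8 to 703 ± 76.2, and GADD45A rose 1.39-fold. Of 33 genes of DNA damage response and repair, 6 rose, 4 fell and 23 did not pass (camera adjusted p = 0.627), with WEE1 the largest rise and RPA3 up 1.34-fold, while XRCC1, on the lower part of chromosome 19, fell 1.34-fold. The BCL2 family and apoptosis inhibitors had 5 risen, 6 fallen and 13 not passed of 24 (camera adjusted p = 0.694), with the pro-apoptotic BIK up 2.799-fold, from 57.1 ± 6.52 to 162 ± 23.7, BCL2L11, which encodes BIM, up 1.504-fold and BAX, on the lower part of chromosome 19, down 1.33-fold. Of 37 chromatin acetylation and Polycomb regulators, 8 rose, 10 fell and 19 did not pass (camera adjusted p = 0.827). The Polycomb gene BMI1 fell 2.17-fold, from 58.3 ± 17.3 to 25.9 ± 6.67, CBX7, in the higher region of chromosome 22, rose 1.51-fold, and the deacetylase gene SIRT1 fell 1.46-fold. Of 12 histone genes, 3 rose, 2 fell and 7 did not pass (camera adjusted p = 0.495), with HIST1H1C up 1.38-fold. In all 7 of these lists the counts were the same adjusted over the list alone.

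Among metabolic lists, glycolysis had 9 risen, 8 fallen and 6 not passed of 23 (10 and 8 adjusted over the list alone; camera adjusted p = 0.508). SLC2A1, the glucose transporter GLUT1, rose 1.51-fold, from 20706 ± 445 to 31287 ± 933, and HK1 and PFKM rose 1.36-fold and 1.34-fold, while 3 of the 8 that fell, ENO1, GPI and LDHA, lay in the lower regions of chromosomes 1, 19 and 11. The hypoxia list had 3 risen, 8 fallen and 11 not passed of 22, the same adjusted over the list alone (camera adjusted p = 0.495), with NDRG1 up 1.66-fold and ANGPTL4, a secreted inhibitor of lipoprotein lipase, down from 58.2 ± 9.21 to 4.31 ± 1.43. Targets of NRF2 had 12 risen, 6 fallen and 5 not passed of 23 (12 and 7 adjusted over the list alone; camera adjusted p = 0.214). The ferritin chains parted, with FTH1 up 1.79-fold, from 4577 ± 188 to 8252 ± 1177, and FTL, on the lower part of chromosome 19, down 2.03-fold, from 2584 ± 82.1 to 1272 ± 87.5, and both have many pseudogenes that can share reads. Cholesterol biosynthesis had 5 risen, 5 fallen and 17 not passed of 27, the same adjusted over the list alone (camera adjusted p = 0.739), with SQLE, squalene epoxidase, down 1.44-fold. Of 34 cytosolic ribosomal protein genes, 17 rose, 7 fell and 10 did not pass (18 and 7 adjusted over the list alone; camera adjusted p = 0.227), and RPL7A rose 1.31-fold, from 4718 ± 202 to 6186 ± 39.4. All 7 that fell, RPS16 and RPS19 among them, lay in the lower regions of chromosomes 11 and 19, which held no other tested member of the list. The mean of this list was 0.04 and turned to -0.003 under quantile normalisation.

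Epithelial markers had 5 risen, 11 fallen and 8 not passed of 24 (6 and 13 adjusted over the list alone; camera adjusted p = 0.123). LSR, a component of tricellular junctions encoded in the lower part of chromosome 19, fell 1.57-fold, and OCLN, occludin, 1.53-fold, while CLDN4 rose 1.47-fold. Mesenchymal markers had 5 risen, 11 fallen and 5 not passed of 21, the same adjusted over the list alone (camera adjusted p = 0.0840). CDH2, N-cadherin, fell 6.52-fold, from 100.1 ± 14.5 to 14.6 ± 3.16, TGFB2 from 63.1 ± 9.9 to 8.62 ± 1.61, and LOX, which crosslinks collagen, 2.197-fold. FN1, fibronectin, fell 3.37-fold in limma (adjusted p = 3.76e-05) but stood at 139 in GemR replicate 1 against 27.8 in each of the other GemR libraries. The Par libraries stood at 156, 212 and 131, so GemR replicate 1 lay within the Par range. The log2 fold change of FN1 went from -1.75 to -2.51 without GemR replicate 1, and the call was lost in DESeq2 and in limma without trend. The mesenchymal list passed without GemR replicate 1 (camera adjusted p = 0.0153) and with no filter (0.0148), in a range of 0.0148 to 0.399. Of 13 stem cell markers, 3 rose, 8 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0542). It passed without GemR replicate 1 (0.0384) or 3 (0.0322), with no filter (0.0190) and with thinned reads (0.0446), in a range of 0.0190 to 0.521. In it SOX9, a transcription factor of duct cells, fell 2.09-fold, from 488 ± 51.7 to 234 ± 44.1, and NES rose 2.002-fold. Markers of other cell types were sparse. Of 14 fibroblast markers 4 were tested and all of these fell, COL3A1, PDPN (5.01-fold), COL1A1 (1.901-fold, from 2139 ± 109 to 1124 ± 24.3) and COL1A2, which stood at 65.1 in GemR replicate 1 and at 10.3 and 8.62 in the others, below all Par libraries. Without GemR replicate 1 its log2 fold change went from -2.96 to -3.85. Blood cell markers had 3 tested, of which 0 rose and 2 fell, the actin regulator genes CORO1A, from 28.7 ± 7.94 to 15.2 ± 5.19, and LCP1, by 1.09-fold. The call of LCP1 was lost with each library left out (log2 fold change -0.14 to -0.11), with no filter, without trend and with thinned reads. That of CORO1A was lost without Par replicate 1 (-0.81), Par replicate 3 (-0.74) or GemR replicate 3 (-0.62), in DESeq2 and without trend. Endothelial markers had 2 tested, with PECAM1 up 1.43-fold and CDH5 down 2.898-fold, and of the acinar and islet markers 1 was tested and fell, BHLHA15, from 31.4 ± 7.56 to 15.03 ± 1.96. CORO1A and BHLHA15 were named after their values were seen. The neuronal and neuroendocrine markers had 3 risen, 2 fallen and 2 not passed of 7, with SNAP25, a synaptic vesicle fusion protein, down 2.12-fold and NEFL, neurofilament light chain, up 2.46-fold (camera adjusted p = 0.618), and with TMM or quantile scaling 1 of the 7 fell. Of the mitochondrially encoded genes, 0 were listed, so this list gave no value.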

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

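Reads thinned to equal depth and the tests without the genes of shifted regions were added after the data were seen. STIM1 stayed past the threshold in each setting run, with a log2 fold change of 3.75 to 3.90 with a library left out. The number of genes called, 5647, fell to 666 (289 higher and 377 lower) with a 2-fold minimum, and otherwise ranged from 4187 (adjusted p under 0.01) to 6151, with 4775 to 5394 when a library was left out. The number of gene lists called, 4, became 10 with no filter on low values, 9 with reads thinned to equal depth, 9 without the genes of shifted regions, 0 with an estimated correlation, 17 with fry and 3 to 8 with a library left out. With no filter, thinned reads or a library left out, lists outside the 27 can reach 5 tested genes and enter these counts. The shifted regions were found from the same fold changes, so leaving their genes out is not an independent test. The number of shifted regions, 11, became 3 with windows of 11 genes.

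In lists that did not pass, the direction given by the test turned in some settings, as did the sign of a gene that did not pass. The mean kept its sign for ABC transporters (-0.075 in the main run), calcium entry (-0.032), gemcitabine genes (0.222) and, under fry, cholesterol biosynthesis (0.00404). It changed sign with a minimum of 50 for chromatin regulators (-0.071 in the main run) and neuronal markers (0.167). Where the test of a list turned direction, its mean log2 fold change was -0.167 (ABC transporters, no filter) and -0.15 (the same, minimum of 50), 0.00194 (chromatin regulators, minimum of 50), -0.108 (neuronal markers, minimum of 50), -0.0374 (calcium entry, DESeq2) and -0.0321 (the same, fry), 0.00404 (cholesterol biosynthesis, fry), and 0.0202 (gemcitabine genes, without the genes of shifted regions). With a library left out, the mean ranged from -0.108 to -0.0226 for ABC transporters, -0.0360 to 0.0384 for cholesterol biosynthesis and -0.0848 to -0.0520 for chromatin regulators, and the test turned in part of these. STIM2 turned to -0.0317 with reads thinned to equal depth and ranged from -0.00973 to 0.0469 with a library left out. The replicate number as a block raised the number of genes called to 6151, and of the 5647 called without it 5636 were also called with it. The labels do not pair the libraries by these numbers. The deviations of libraries with the same number correlated by only 0.031, 0.093 and 0.040, though each correlated best with its own number. The data therefore leave a weak pairing open.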

Other observations

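The gene families named here, picked from 17 looked at, the genes at which a library lay apart, the fibroblast test and the tests of scaling and depth were chosen after the values were seen, and the other tests of the chromosome 11 and chromosome 19 patterns were set out before their results were seen. S100 genes, which encode small calcium-binding proteins, were mostly higher in GemR, with 9 risen and 1 fallen of 11 tested (median log2 fold change 0.57). S100A4 rose 2.89-fold, from 48.4 ± 2.46 to 142 ± 6.48 normalised counts, S100A14 2.37-fold and S100A6 1.86-fold, from 8825 ± 289 to 16408 ± 719, while S100A9 fell from 20.9 ± 1.602 to 6.36 ± 1.29. These 4 genes lie close together on chromosome 1 (153357854 to 153616325). Changes of neighbouring S100 genes may therefore not be separate observations, and a local shift was not told apart from a change of the family. Of 27 genes of protein entry into the endoplasmic reticulum and of retrieval to it, 0 rose and 14 fell, among them the translocon gene SEC61A1 (1.23-fold) and the KDEL receptor genes KDELR1 (1.67-fold) and KDELR3 (1.598-fold), though KDELR1 and SSR1 lie in regions where most genes fell. Of 212 solute carriers, 25 rose and 78 fell, with the glutamine transporter gene SLC1A5, in the lower part of chromosome 19, down 1.97-fold and the serine transporter gene SLC1A4 down 1.95-fold. The HLA class II accessory genes HLA-DMB (101.5 ± 8.71 to 13.8 ± 7.003) and HLA-DMA (83.3 ± 11.1 to 30.001 ± 2.18) fell. These directions were the same under TMM, equal totals and quantile scaling.

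In 2 further families of the 17 all members that fell lay in the shifted regions, whereas 0 of the 5 fallen keratins, 0 of the 5 fallen claudins, 0 of the 9 fallen collagens and 1 of the 7 fallen tetraspanins did so. The lower regions held 0 tested keratins, claudins or collagens and 1 tetraspanin, so this contrast was fixed by where the genes lie. Of 36 proteasome subunit genes, 17 rose and 4 fell, and all 4 that fell (PSMA1, PSMC4, PSMD13 and PSMD8) lay in the lower regions of chromosomes 11 and 19, which held no other tested member of the family. Likewise the 3 mucin genes that fell, of 5 tested, were MUC2, MUC5AC (3.02-fold, from 1479 ± 273 to 493 ± 111) and MUC5B, neighbours before STIM1 on chromosome 11 (the call of MUC2 was lost without Par replicate 2 or GemR replicate 1, each at a log2 fold change of -0.23, in DESeq2 and, as for MUC5B, without trend), while MUC4 rose 2.38-fold. Genes were counted where 1 library lay more than 1 log2 unit (pseudocount 8) from the mean of the others of its group, which differed by less than 0.5. Such genes numbered 2 above and 2 below for Par replicate 1, 3 and 10 for Par replicate 2, 5 and 5 for Par replicate 3, 8 and 0 for GemR replicate 1, 5 and 0 for GemR replicate 2 and 2 and 0 for GemR replicate 3. RPPH1, RN7SK and RMRP in GemR replicate 2 and RN7SK and RN7SL2 in Par replicate 3, higher there, are RNAs without a poly(A) tail. The 8 genes of GemR replicate 1 were MYLK3 and 7 that are mostly stromal, GREM1, COMP, ACAN, ITGA11, SPARC (31.3 against 1.59 and 0.958 normalised counts), COL1A2 (65.1 against 10.3 and 8.62) and FN1 (139 against 27.8 and 27.8). Where these reads came from was left open, and the values of COL1A2, FN1 and the mesenchymal list are uncertain in that library.

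The genes from STIM1 to SBF2-AS1 rose together by a median of 1.84 on the log2 scale, between flanks that fell. The scaling of the libraries and the greater depth of GemR act on genes wherever they lie, but the block median exceeded that of the flank closer in value by 2.34, with interquartile ranges that did not overlap. The limits of the block and of its far flank were drawn from the same fold changes. The size of this gap was thus in part fixed by the choice and is not independent support. Reads shared between genes that overlap in the annotation used here, or within the TRIM, zinc finger and ribosomal families, do not account for the whole rise. The 12 block genes with no such overlap and outside these families had a median of 1.89 (lower quartile 1.73). These 12 genes belong to the block chosen from the same fold changes. Other paralogs, and overlaps in the annotation used for counting, were not examined. A higher dosage of the whole block, by a gain of DNA or by altered chromatin, may be the cause as a hypothesis, since the 33 block genes left out of the test for low counts, which had no part in finding it, rose by 1.12 on the log2 scale when summed, from 36.7 ± 4.93 to 79.6 ± 9.30. That rise was smaller than the block median of 1.84 and lay below the lower quartile of the tested genes (1.44). An equal change of all block genes is therefore not shown. Genes that overlap others were kept in this sum and the kit does not mark strand. Reads of the tested block genes may therefore have entered it, so its independence of them is not shown. RRM1 and STIM1, at 16.6-fold and 14.03-fold, lie far above the 3.59-fold median of the block, so that dosage of the whole block alone leaves part of their rise open, and no DNA measurement was analysed here.

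The fall of chromosome 19 beyond 23 Mb had a median of -0.48. GC content and transcript length do not account for it, since the median was still -0.47 over 484 genes after a trend in both was removed, nor do the zinc finger genes that cluster there, since the 335 genes not named as such had a median of -0.47 and the 295 ZNF genes elsewhere one of 0.02. Scaling and depth would have moved the chromosome alike on both sides of 23 Mb, but the median beyond minus that before was -0.55, with interquartile ranges that did not overlap. The cut at 23 Mb was placed after the values were seen, so the size of this gap was in part fixed by the choice. A lower dosage of the region, such as a lost copy in part or all of the GemR cells, may be the cause as a hypothesis, since the 207 region genes with counts too low for the test fell by 0.60 on the log2 scale when summed, from 601.1 ± 29.8 to 395.9 ± 6.25. Overlapping genes were kept in this sum too, so reads of the tested region genes may have entered it. Loss of DNA and silencing of the region were not told apart by these data.

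COL3A1 and COL1A2 were higher in Par, where COL3A1 stood at 3620.3 ± 143. Fibroblasts in the Par cultures might bring such reads, but the median of 6 fibroblast genes in Par was 0.0662% of the COL3A1 level. This was set against COL3A1 alone and says nothing of COL1A2, which stood at only 149.7 ± 17.9 in Par. Of the 6 genes, COL1A1 stood at 2139 (59.1% of COL3A1) but DCN at 5.35, LUM at 2.61, PDGFRB at 2.18, POSTN at 0.774 and FAP at 0.387. The 6 genes were chosen after the values were seen and leave out PDPN of the fibroblast list. No fibroblast sample was at hand to show what levels to expect. The values show that most of these genes were near absent in Par, but the test cannot exclude fibroblasts. A loss of collagen expression by the resistant cancer cells stays open as a hypothesis that was not tested, as does selection of a subclone.

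The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split called 5647 genes, the highest of the other splits called 0, and 1 of the 10 splits, the real one, gave as many genes. Every other split put Par and GemR libraries into the same group, so their difference became spread within groups. The 0 was thus largely fixed in advance, whatever the source of the difference.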
